A study of Mus musculus with 6 samples.

How the data were processed

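Gene expression was measured in mouse bone marrow LSK cells, the lineage-negative, Sca1-positive and c-Kit-positive fraction that holds hematopoietic stem cells and multipotent progenitors. Per the labels, mice of the C57BL/6 strain carried the Mx1-Cre transgene with either unmodified Srf alleles (control) or loxP-flanked Srf alleles (SRF-null). Both genotypes received pIpC, a double-stranded RNA that switches on the interferon-inducible Mx1-Cre recombinase, as 3 injections of 200 µg given 2 days apart to mice 6 weeks old, and cells were taken 35 days after the last injection. LSK cells were sorted by flow cytometry from pooled animals. Per the labels' protocols, 30 ng of total RNA was amplified and biotin-labelled with a NuGEN kit and hybridised to Affymetrix arrays. The groups hold 3 control and 3 SRF-null arrays. How many animals each pool held, and whether any animal served more than 1 pool, is not given in the sources used here, so the p-values measure only the spread between these samples.

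The deposited table holds 1 intensity per probe set and array on a linear scale, and this unit was read from the values, which are never negative and not whole numbers. The summary algorithm, the background correction and the scaling the authors used to obtain these intensities are not given in the sources used here. The study's description and the annotation of the table differ on the array type, and the table, with 45101 probe sets, was used as it stands. Of these probe sets 64 were Affymetrix controls, 34958 named 1 gene in the platform annotation, 932 named several genes and 9160 named none in the table used here. Of the probe sets with 1 gene, 34754 were found by gene ID in a RefSeq gene table (assembly GRCm38.p6, used only for names and gene order), and 0 had a newer symbol. The array type gives no build, so no coordinates are printed.

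Intensities were converted to log2(value + 16), and fold changes are on this scale, which understates the change of dim genes. The median log2 value differed between arrays by 0.51, above the limit of 0.1 set in advance, so the arrays were quantile normalized, while their upper quartiles differed by only 0.08. Between 26.0% and 27.0% of probe sets lay under a signal of 16 on each array. No detection calls were used, and the number of arrays limits the precision of every value. Each gene was represented by the probe set with the highest mean over the 6 arrays among those naming that gene alone, which gave 18193 genes, with no filter on dim genes. Of the 105 genes the naming rule gave, 63 had several probe sets, and 16 of these had at least 1 probe set with a difference of opposite sign.

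SRF-null arrays were compared with control arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, moderated test in both directions, genotype as the only term), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Gene lists were tested with camera from limma at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 24 lists, and sex-linked genes were kept apart as a check of the samples. A list's mean is given with the standard error between arrays, which takes no account of any pairing of arrays. The lists cover actin cytoskeleton and immediate early targets of SRF, SRF cofactors, integrins and adhesion, hematopoietic stem cell genes, multipotent and lymphoid progenitor genes, and markers of granulocytes, monocytes and macrophages, B cells, T and NK cells, erythroid cells, megakaryocytes, mast cells and basophils, dendritic cells, and stromal and endothelial cells. They also cover cell cycle genes, cell cycle inhibitors and quiescence genes, p53 targets, interferon response genes, apoptosis regulators, stress and dissociation genes, ribosomal protein genes and oxidative phosphorylation genes. Of the 24 lists 1 is not reported here, although it entered the adjustment and the counts of lists. The lists name 775 different genes, of which 695 were measured. The 3′ to 5′ signal of the Actb and Gapdh control probe sets, a sign of RNA quality, was taken on log2(value + 16) before normalization and compared with an exact permutation test on both sides, for which 3 against 3 arrays cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9.

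The grouping, the tests, the gene lists, the rule for named genes and the alternatives were set before the data were examined, except where a choice is said to have been made afterwards. The rule names Srf, then among genes past the threshold whose groups do not overlap up to 12 with the largest rise and 12 with the largest fall, filled to 6 in each direction by smallest p with genes said not to have passed, and up to 4 members of each list with the smallest p.

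Replicates carry the numbers 1 to 3 in both genotypes, and whether equal numbers pair the arrays was checked from the correlation of their deviations from the group means. Over all 18193 genes this correlation was 0.198, 0.125 and 0.367 for the arrays numbered 1, 2 and 3, and each array correlated best with its own number. Since every value was above 0.1, the numbers were taken to pair the arrays. Over the 9096 genes above the median level, however, the correlation for number 2 was 0.0946, and SRF-null 2 correlated slightly better with control 1 (0.0979). The pair numbered 2 is therefore uncertain. The pairing comes from these correlations alone and not from the labels. The fit without a block for the number remained the reported one, and the blocked values are given where they change a call.

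The tests were checked on simulated data with 200 of 18193 genes changed, 3 arrays per group and 20 simulations per fold. Adjusted p-values recovered 23.4% of the genes changed 2-fold, 77.2% of those changed 4-fold and 90.2% of those changed 8-fold. These shares hold for 200 genes changed by the same fold with independent noise, so they do not give the share that the fit would recover in the data. A list lowered 2-fold was found in 20 of 20 simulations with the preset and with the estimated correlation, while other lists were called 3 and 0 times in total. The simulated genes were independent of each other, whereas the estimated correlation in the data reached 0.641 (cell cycle genes). These counts therefore do not show how often the preset correlation miscalls lists of correlated genes.

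Alternatives were a block for the replicate number, median centring in place of quantile normalization, a filter on dim genes, a trended and robust variance, array weights, other rules for the probe set of a gene, offsets of 1 and 64, all probe sets, other thresholds, an estimated correlation or fry for the lists, and leaving out each array in turn. Values as deposited, upper quartile scaling and a fit without the arrays of 1 sex were added after seeing the data. For the actin cytoskeleton list, unlisted genes of the same level were the 100 nearest in mean signal to each member, and the Y-linked signal was the mean of Kdm5d, Eif2s3y and Uty relative to the male-only array.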

Results

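SRF is a transcription factor that acts with its cofactors on actin cytoskeleton genes and on immediate early genes. Its deletion in mouse LSK cells was examined on 6 arrays, 3 from control and 3 from SRF-null pools of sorted cells, and the question was which transcripts differ between these genotypes. The arrays had a median signal of 200.5 to 292.1 and an upper quartile of 5024 to 5320 per array before normalization. Spearman correlations across the 18193 genes were 0.983 to 0.986 between arrays of 1 genotype and 0.982 to 0.987 between arrays of different genotypes. Values are normalized log2 signals, given as mean ± SD over n = 3 arrays per group, and differences are SRF-null minus control.

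The targeted gene, Srf, was lower in SRF-null cells on its brighter probe set, at 12.60 ± 0.19 against 13.03 ± 0.02 in control cells. This is a difference of −0.42 (SE 0.13), or 1.34-fold, and all 3 SRF-null arrays lay below all 3 control arrays. The limma p was 0.0191 and did not pass adjustment over all genes (adjusted p = 0.771). The dimmer probe set differed by 0.10 (SE 0.35), less than the spread between arrays. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, so neither value measures how complete the deletion was.

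**Figure D1:**
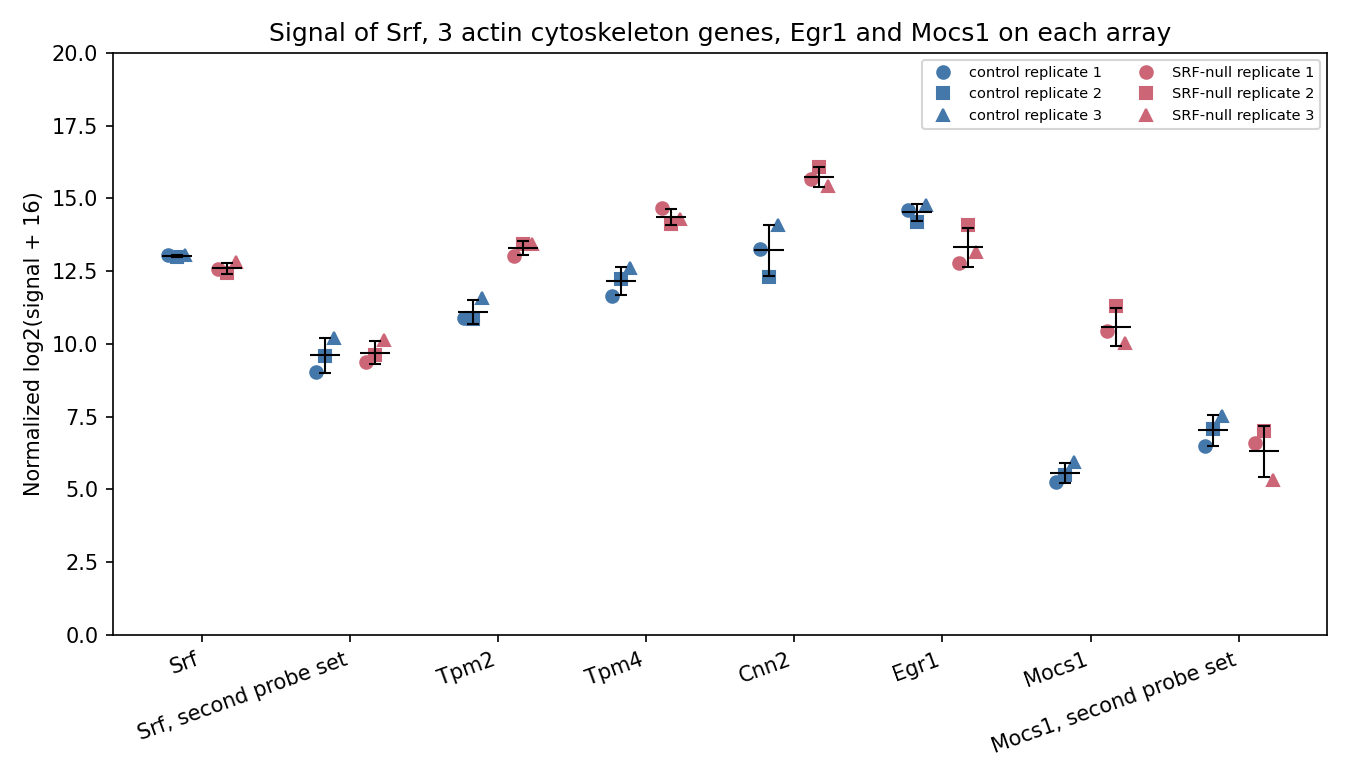
Normalized log2(signal + 16) on each of the 6 arrays for Srf, the actin cytoskeleton genes Tpm2, Tpm4 and Cnn2, the immediate early gene Egr1 and Mocs1, with the second probe sets of Srf and Mocs1 (blue, control; red, SRF-null; circles, squares and triangles, replicates 1, 2 and 3; bars, mean ± SD, n = 3). Srf averages 13.03 in control and 12.60 in SRF-null arrays, Tpm4 12.16 and 14.37, and Mocs1 5.57 and 10.58, while the second Mocs1 probe set averages 7.03 and 6.31.

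Among all genes, the differences with the smallest p included higher tropomyosin transcripts and a very large difference for 1 enzyme gene. Mocs1, which encodes an enzyme of molybdenum cofactor synthesis and lies 51 genes from Srf in gene order, was 32.4-fold higher in SRF-null cells, at 10.58 ± 0.65 against 5.57 ± 0.34 (difference 5.02, SE 0.36, limma adjusted p = 0.121). It was dim in control cells, so the fold depends on the offset, and the difference was 5.57 with an offset of 1 and 4.05 with an offset of 64. Tpm2 and Tpm4, which encode tropomyosins that run along actin filaments, were higher by 2.20 (SE 0.24) and 2.21 (SE 0.28), 4.59-fold and 4.62-fold, with limma adjusted p-values of 0.388 and 0.467. The other genes with the smallest p among those higher were Tmem108 (2.01), the vesicular monoamine transporter gene Slc18a1 (2.18) and the Fc receptor-like gene Fcrl1 (1.29). Among those lower they were Npdc1 (−1.37), the Notch ligand gene Jag1 (−1.68), the metalloproteinase inhibitor gene Timp3 (−1.76), the calpain family gene Capn15 (−1.02), Pgap6 (−0.86) and Rhof (−1.08). In each of these 12 genes the 3 SRF-null arrays lay on 1 side of the 3 control arrays, and none of the 12 passed the adjustment.

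By limma, 0 of 18193 genes passed an adjusted p of 0.05 or of 0.1, and 1044 genes had an unadjusted p under 0.05 (529 higher and 515 lower in SRF-null cells) where 910 are expected by chance if the arrays are independent. The groups did not overlap for 1926 genes, 10.6% of those tested, where chance gives 10% for arrays that are not paired. With the replicate number as a block the count past the threshold was again 0, and 1478 genes had an unadjusted p under 0.05. The call for Mocs1 changed with the fit, since its adjusted p was 0.00271 after median centring and 0.00935 with a trended and robust variance, and its second probe set was lower, at −0.72 (SE 0.50).

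Actin cytoskeleton targets of SRF were called higher as a group in SRF-null cells at the preset correlation. Of 45 measured members 28 were higher and 17 lower, with a mean difference of 0.28 ± 0.08 (SE between arrays). The median was only 0.08, so members with large differences weighed on the mean. Camera's adjusted p was 0.00273 at the preset correlation, and the adjusted p = 0.608 with an estimated correlation. Tpm2, Tpm4, the calponin gene Cnn2 (2.52, SE 0.45, 5.75-fold) and the cardiac actin gene Actc1 (0.94, SE 0.14) were higher on 3 of 3 arrays. These 4 members passed a limma threshold of 0.05 adjusted over the list alone, while 0 passed over all genes tested. Actc1 was dim in both groups, at 4.88 and 5.81. Of the members chosen after their values were seen, cytoplasmic actin Actg1 was higher by 1.12 (SE 0.29) and Wdr1, whose product speeds actin filament turnover, by 0.62 (SE 0.16), whereas the gene of the filament-severing protein destrin, Dstn, differed by −0.50 (SE 0.18). The other 3 probe sets of Tpm2 differed by 1.03, 2.17 and 2.31.

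Immediate early targets of SRF did not pass as a group, with 16 of 28 members lower, a mean difference of −0.10 ± 0.34 and a camera adjusted p of 0.127. The 4 members with the smallest p were all lower in SRF-null cells, and all encode transcription factors. They were Egr1 (−1.20, SE 0.36), Junb (−0.86, SE 0.23), Fosl2 (−0.81, SE 0.23) and Fosl1 (−2.61, SE 0.75), and 0 members passed over all genes or adjusted over the list alone. Fosl1 was at the bottom of the scale on the SRF-null arrays (4.03 to 4.13), so the size of its difference depends on the offset and ranged from −5.42 to −1.35 over the alternatives. Without SRF-null replicate 2 the camera adjusted p of this list was 0.0102. The SRF cofactor list (8 members, mean 0.22 ± 0.15, adjusted p = 0.354) did not pass, and the genes of the cofactors MRTF-A, Mrtfa (0.10, SE 0.11), and ELK1, Elk1 (0.12, SE 0.15), differed by about their standard errors. Integrins and adhesion genes (49 members, mean 0.00 ± 0.08, adjusted p = 0.828) did not pass either. Within the adhesion list Jam3 differed by −1.14 (SE 0.22) on its brighter and by 0.79 (SE 0.31) on its dimmer probe set, the leukocyte integrin gene Itgb2 by 0.83 (SE 0.21) and Itgb3 by −0.70 (SE 0.26), and its members' mean test statistic had the opposite sign to their median and mean.

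**Figure D2:**
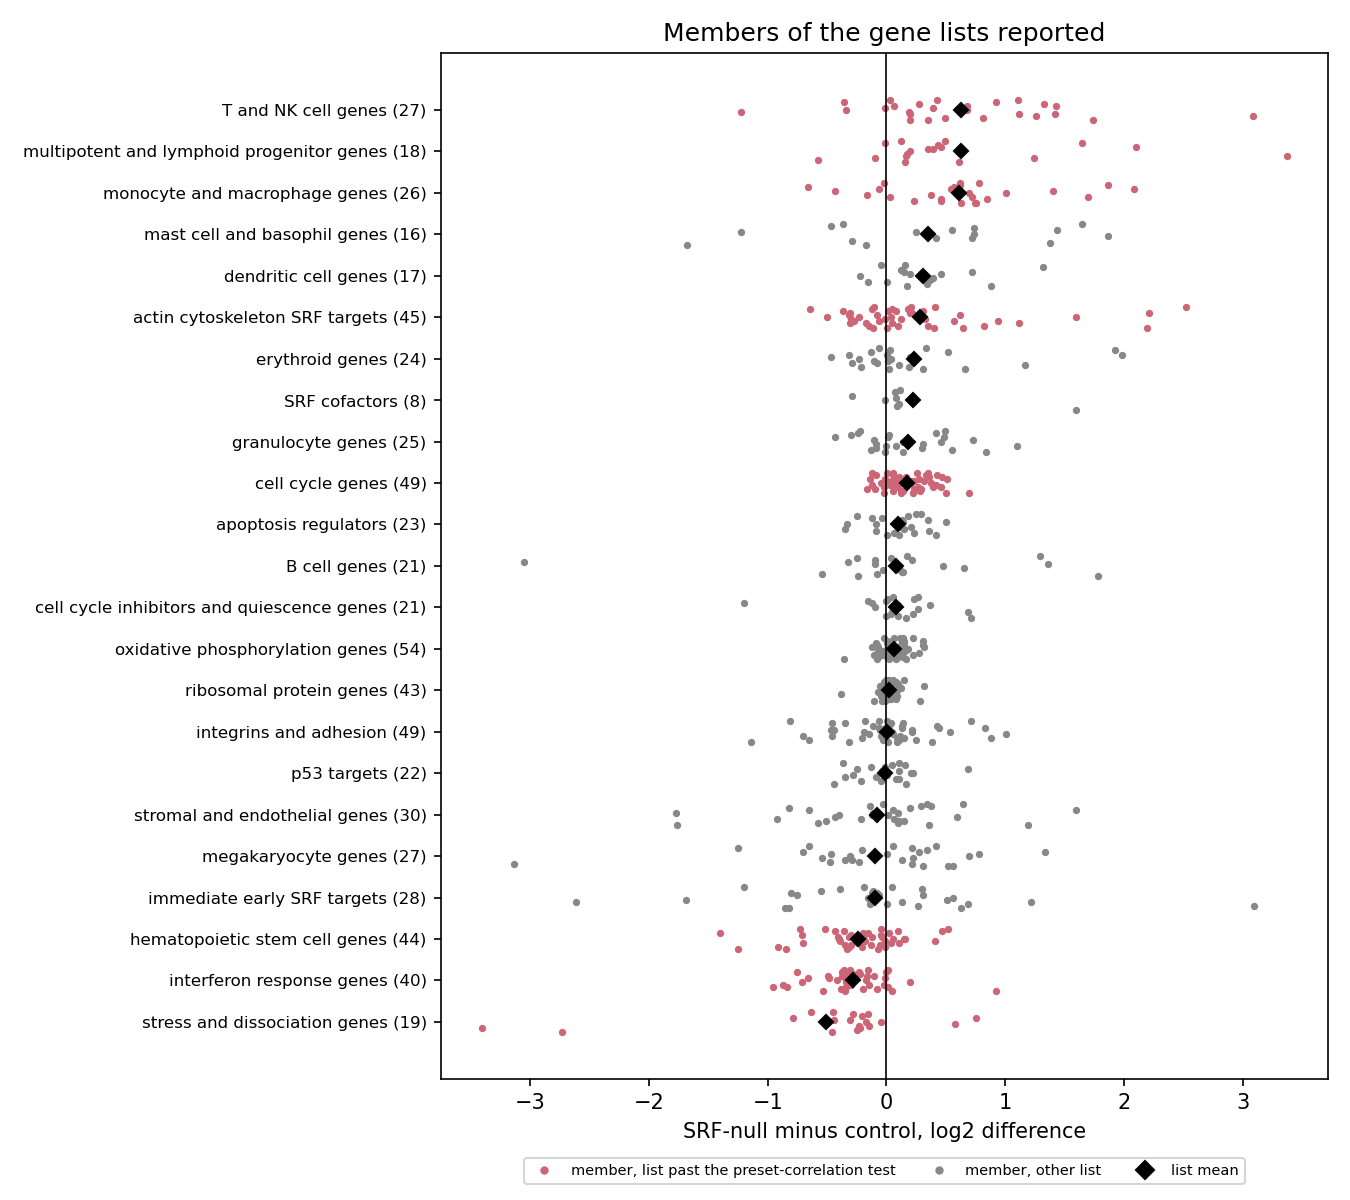
Log2 difference, SRF-null minus control, of each measured member of the gene lists reported, with the number of measured members in parentheses (points, genes; diamonds, list means; red, the 8 lists past camera's threshold at the preset correlation; grey, the other lists). Means range from 0.63 for T and NK cell genes to −0.51 for stress and dissociation genes, and the actin cytoskeleton targets average 0.28 with 28 of 45 members above 0.

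Genes of multipotent and lymphoid progenitors were called higher in SRF-null cells and genes of hematopoietic stem cells lower at the preset correlation. Their estimated correlations were 0.282 and 0.259. Array means of the genotypes overlapped in both lists, and SRF-null replicate 3 was the extreme array in each (14.36 and 13.055). Within every number pair, if the pairing holds, the SRF-null mean was higher for the progenitor list and lower for the stem cell list. Of 18 measured progenitor genes 15 were higher and 3 lower, with a mean of 0.63 ± 0.33 and a camera adjusted p of 3.79e-05, and the adjusted p = 0.608 with an estimated correlation. The interleukin-7 receptor gene Il7r was higher by 2.11 (SE 0.50, 4.30-fold) and Satb1, which encodes a chromatin organizer of lymphoid cells and lies 59 genes from Srf in gene order, by 0.61 (SE 0.14), and these 2 passed a limma threshold adjusted over the list alone. The chemokine receptor gene Ccr9 differed by 3.38 (SE 1.01) and Cd52 by 0.50 (SE 0.16), and 0 members passed over all genes tested. Ccr9 was dim on control replicate 2 (4.86, against 8.85 and 7.33 on the other controls), and its difference ranged from 1.76 to 4.29 over the alternatives. Of 44 measured stem cell genes 34 were lower and 10 higher, with a mean of −0.24 ± 0.17 and a camera adjusted p of 0.000536, and the adjusted p = 0.683 with an estimated correlation. The angiopoietin receptor gene Tek differed by −0.84 (SE 0.18), Tgm2 by −0.73 (SE 0.28), Mycn by −0.71 (SE 0.22) and Fgd5 by −0.70 (SE 0.24), and 0 members passed over all genes or adjusted over the list alone. The stem cell list lost its call without control replicate 1 (adjusted p = 0.197) or without SRF-null replicate 3 (0.141).

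Markers of mature T and NK cells and of monocytes and macrophages were also called higher in SRF-null cells at the preset correlation. Their estimated correlations were 0.177 and 0.279, and the array means of the genotypes overlapped in each list. Within every number pair, if the pairing holds, the SRF-null array had the higher mean in both lists. In the T and NK cell list 23 of 27 members were higher, with a mean of 0.63 ± 0.36 and a camera adjusted p of 3.79e-05, and the adjusted p = 0.608 with an estimated correlation. Cd7 was higher by 1.74 (SE 0.27, 3.33-fold) and was the 1 member that passed adjusted over the list alone, while the T cell receptor zeta gene Cd247 (0.68, SE 0.17), the NK receptor gene Klrd1 (1.42, SE 0.39) and Cd4 (1.11, SE 0.33) did not pass. With only the genes above the median level this list's adjusted p was 0.167. In the monocyte and macrophage list 21 of 26 members were higher, with a mean of 0.61 ± 0.44 and a camera adjusted p of 5.06e-05, and the adjusted p = 0.683 with an estimated correlation. The lysosomal protease gene Ctss differed by 0.75 (SE 0.18), the mannose receptor gene Mrc1 by 2.08 (SE 0.54), the complement gene C1qa by 1.70 (SE 0.55) and the scavenger receptor gene Cd163 by 0.78 (SE 0.30), and 0 members passed over all genes or adjusted over the list alone. Without SRF-null replicate 3, the array on which this list's mean was highest (11.09 against 9.74 and 10.49 on the other SRF-null arrays), the adjusted p was 0.0906.

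Markers of the other lineages did not pass at the preset correlation. The dendritic cell list had 14 of 17 members higher (mean 0.31 ± 0.48, adjusted p = 0.104) and the adjusted p = 0.683 with an estimated correlation. It passed in 6 of 20 alternatives, which were the replicate block (0.00757), median centring (0.0309), the mean of all probe sets of a gene (0.0240) and the fits without control replicate 3, SRF-null replicate 1 or SRF-null replicate 2 (0.0441, 0.00744 and 0.0255), and it turned without SRF-null replicate 3 (0.824). Itgax (0.88, SE 0.41) and Ccr7 (0.72, SE 0.41) had the smallest p in it. The mast cell and basophil list (16 members, mean 0.35 ± 0.42, adjusted p = 0.354) held both the mast cell chymase gene Cma1 at −1.68 (SE 0.40) and Ms4a2, the beta chain of the IgE receptor, at 1.65 (SE 0.69), and passed without control replicate 3 (0.0212). Granulocyte genes (25 members, mean 0.18 ± 0.26, adjusted p = 0.354), with Clec4d at 0.84 (SE 0.25) and Gfi1 at −0.43 (SE 0.18), did not pass. Neither did erythroid genes (24 members, mean 0.23 ± 0.38, adjusted p = 0.416), with Trim10 at 0.67 (SE 0.18), Tspo2 at 1.99 (SE 0.72) and Nfe2 at −0.29 (SE 0.12). B cell genes (21 members, mean 0.08 ± 0.93, adjusted p = 0.444) did not pass either, with Ebf1 at 1.79 (SE 0.93). In that list Igll1 differed by −3.06 (SE 1.99) on its brighter and by 1.65 (SE 1.51) on its dimmer probe set. Without SRF-null replicate 1 the erythroid and B cell lists had adjusted p-values of 0.000291 and 0.0250, and without control replicate 2 and SRF-null replicate 1 together the erythroid and granulocyte lists had 0.00257 and 0.0332. Megakaryocyte genes (27 members, adjusted p = 0.575) had a median of 0.06 and a mean of −0.09 ± 0.30, with Plek at 0.56 (SE 0.13). Stromal and endothelial genes (30 members, adjusted p = 0.459) had a median of 0.03 and a mean of −0.08 ± 0.15, and camera's direction for both lists followed the mean. In the stromal and endothelial list 1 member, Timp3, passed adjusted over the list alone, and the endothelial receptor genes Eng (−0.66, SE 0.16) and Tie1 (−0.93, SE 0.23) were lower and the mural cell receptor gene Pdgfrb (0.65, SE 0.20) higher on 3 of 3 arrays without passing.

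At the preset correlation interferon response genes and stress and dissociation genes were called lower in SRF-null cells, and cell cycle genes higher. The estimated correlations between members were 0.488, 0.298 and 0.641, and in each list the array means of the genotypes overlapped. Within every number pair, if the pairing holds, the SRF-null mean was lower for the interferon and stress lists and higher for cell cycle genes. The overlap then lay between pairs. Of 40 interferon response genes 35 were lower, with a mean of −0.28 ± 0.29 and a camera adjusted p of 0.000178, and the adjusted p = 0.683 with an estimated correlation. Gbp2 differed by −0.49 (SE 0.14), Oas2 by −0.87 (SE 0.33) and Tap1 by −0.31 (SE 0.12), whereas Ifi27l2a differed by 0.93 (SE 0.23). Of 19 stress and dissociation genes 17 were lower, with a mean of −0.51 ± 0.37 and a camera adjusted p of 0.00108, and the adjusted p = 0.683 with an estimated correlation. Herpud1 (−0.46, SE 0.16) and Xbp1 (−0.79, SE 0.31), both of the unfolded protein response, had the smallest p. Among genes chosen after their values were seen the heat shock gene Hspa1b differed by −3.41 (SE 2.36), ranging from −5.27 to −1.54 over the alternatives. Of 49 cell cycle genes 39 were higher, by a mean of 0.18 ± 0.22, with a camera adjusted p of 0.00165, and the adjusted p = 0.683 with an estimated correlation. Hmmr (0.70, SE 0.31) and the cyclin gene Ccnb2 (0.51, SE 0.24) had the smallest p. In these 3 lists 0 members passed over all genes or adjusted over the list alone. The interferon call was lost without control replicate 2 (adjusted p = 0.179), the array with the highest mean of that list (14.43), and the list turned to the opposite direction without control replicate 2 and SRF-null replicate 1 together (adjusted p = 0.847), the arrays that carried transcripts of 1 sex. The stress call was lost without control replicate 3 (0.0586), and the cell cycle call without control replicate 1 (0.255), control replicate 2 (0.0636), SRF-null replicate 3 (0.478) or the 2 arrays just named (0.186).

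The remaining lists did not pass. Oxidative phosphorylation genes had 41 of 54 members higher by a mean of 0.06 ± 0.05 (adjusted p = 0.0509), and the adjusted p = 0.683 with an estimated correlation. They passed in 7 of 20 alternatives (0.00645 with a trended and robust variance to 0.0461 with the replicate number as a block), among them the fits without control replicate 2 (0.0206) or SRF-null replicate 2 (0.0389). Uqcrc1 (−0.36, SE 0.15) and Ndufb8 (0.31, SE 0.14) had the smallest p in it. Apoptosis regulators (23 members, mean 0.10 ± 0.11, adjusted p = 0.106), cell cycle inhibitors and quiescence genes (21 members, 0.08 ± 0.06, 0.135), ribosomal protein genes (43 members, 0.02 ± 0.02, 0.444) and p53 targets (22 members, −0.01 ± 0.14, 0.890) had means within 1.5 standard errors of 0. Gadd45b, an inducible stress gene, differed by 0.71 (SE 0.21) and the p53 target Aen by −0.44 (SE 0.15). Over all 24 lists 5 were called higher and 3 lower at the preset correlation, 10 were called with the replicate number as a block, and 0 were called with an estimated correlation or by fry in 1 direction. By fry's mixed test, which asks whether members change in either direction, the actin cytoskeleton targets (adjusted p = 0.000536) and the stromal and endothelial genes (0.0239) passed.

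Sex-linked transcripts set 1 array of each genotype apart from the others. On control replicate 2 the Y-linked genes Kdm5d and Eif2s3y were at 4.0 and 4.37, against 10.54 to 11.98 and 13.06 to 14.50 on the other arrays. On SRF-null replicate 1 Xist, which is expressed from the inactive X chromosome, was at 5.03, against 15.13 to 16.24 on the other arrays. These arrays thus had the transcripts of 1 sex, and the other 4 had those of both. Kdm5d, Eif2s3y and Uty were also higher on every SRF-null array than on any control array, with Kdm5d at 11.84 to 11.98 against 4.0 to 10.57. Usp9y, near the bottom of the scale, overlapped. Xist on the arrays with transcripts of both sexes overlapped too, at 15.575 on control replicate 3 against 15.601 on SRF-null replicate 2. Judged by Kdm5d, Eif2s3y and Uty alone, the share of males went with genotype, which bears on every gene and list. It was examined as a covariate only for the actin cytoskeleton list. The 3′ to 5′ log2 difference of the Actb control probe sets was 1.33 ± 0.14 in control and 1.15 ± 0.32 in SRF-null arrays, and that of Gapdh was 1.06 ± 0.12 and 0.93 ± 0.24. For both, the difference between groups lay within the spread between arrays (exact permutation p = 0.4 for each, n = 3 per group, where 0.1 is the smallest p possible).

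**Figure D3:**
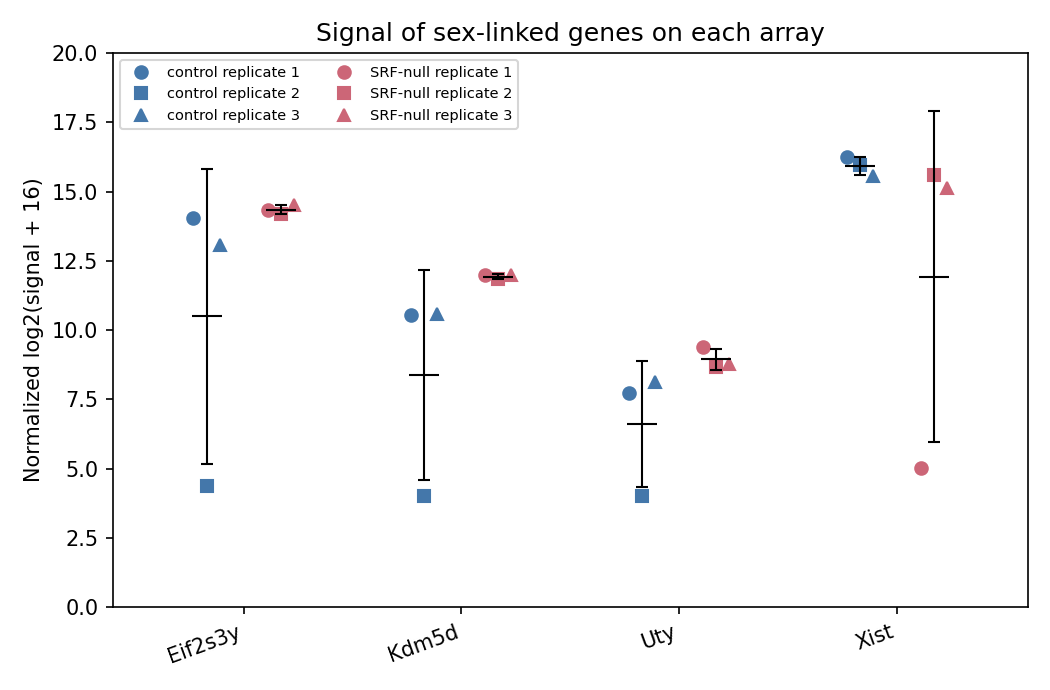
Normalized log2(signal + 16) of the Y-linked genes Eif2s3y, Kdm5d and Uty and of Xist on each of the 6 arrays (blue, control; red, SRF-null; circles, squares and triangles, replicates 1, 2 and 3; bars, mean ± SD, n = 3). Kdm5d is at 4.0 on control replicate 2 and Xist at 5.03 on SRF-null replicate 1.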

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

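The fits on values as deposited, with upper quartile scaling and without the arrays of 1 sex (control 2 and SRF-null 1) were chosen only after the results were seen. Since the arrays were quantile normalized, the planned quantile alternative was the reported fit itself. The number of genes changed was 0 in 18 of 21 alternatives and 1 after median centring (Mocs1), 1 with a trended and robust variance (Mocs1), and 0 to 1 when 1 array was left out. That 1 gene, Ccnb1ip1, passed without control replicate 2 and was named only after its values were seen. Genes at an unadjusted p under 0.05 numbered 647 after median centring, 635 with only the genes above the median level, where fewer genes were tested, 1569 with array weights, 1975 over all probe sets, where more were tested, and 689 without the arrays of 1 sex, where fewer arrays were used. The lists called numbered 0 with an estimated correlation, 0 by fry, 5 (without SRF-null replicate 3) to 11 with 1 array left out, and 8 to 10 in the other fits. The replicate block gave 0 genes changed and 10 lists called, and beyond adding the dendritic cell and oxidative phosphorylation lists it changed no other call. The actin cytoskeleton and the multipotent and lymphoid progenitor lists kept their calls in 18 of 20 alternatives, all but the estimated correlation and fry. Without _x_at or _s_at probe sets Srf differed by 0.10, Mocs1 by −0.72 and Dock2 by 0.23, each opposite to the reported sign because another probe set was read, and the integrin list turned (adjusted p = 0.980). Igll1 turned to 1.66 with an offset of 1, with 1 array left out Hspa1a ranged from −4.55 to 0.13, turning without control replicate 3, and Lyz2 from −0.21 to 0.016, turning without control replicate 1, and Tnfrsf10b turned to 0.051 without the arrays of 1 sex. With only the genes above the median level the erythroid (adjusted p = 0.872) and p53 (0.557) lists turned. Without the arrays of 1 sex the integrin (0.847), interferon (0.847), megakaryocyte (0.809) and ribosomal protein (0.992) lists turned. With 1 array left out, lists that turned at least once had adjusted p-values of 0.621 to 0.980 (integrins), 0.0250 to 0.841 (B cell), 0.000291 to 0.792 (erythroid), 0.237 to 0.877 (megakaryocyte), 0.00744 to 0.824 (dendritic cell), 0.782 to 0.951 (p53) and 0.148 to 0.967 (ribosomal protein). The Gapdh 3′ to 5′ difference between groups ranged from −0.24 to 0.000891 with 1 array left out, the latter without SRF-null replicate 3. Of the values of single genes 2109 kept their sign and side of the threshold, 3 passed (Mocs1 and Ccnb1ip1) and 6 turned, and of those of single lists 416 kept both, 26 lost a call, 19 gained one and 19 turned. Where no cause is named, the cause was not tested. The signal lay under 16 for 26.0% to 27.0% of probe sets on each array, and differences of genes near that level depend on the offset.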

Other observations

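The tests of linked DNA, of exchanged labels, of the scaling, of sex and of cell mixture were chosen only after the results were seen, and so were the genes named in the next paragraph, the neighbours of Srf and Lyz2.

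At least 4-fold differences with no overlap between the groups were found for 22 genes higher and 12 genes lower in SRF-null cells, 3 of them Y-linked, and 0 passed the limma adjustment. Tjp1, which encodes a scaffold protein of tight junctions that binds actin, differed by −3.71 (SE 0.58), at 9.87 ± 1.00 against 13.58 ± 0.71 in control cells (13.1-fold, limma adjusted p = 0.467). Socs2, a feedback inhibitor of cytokine signalling, differed by −2.12 (SE 0.42) and the small heat shock gene Hspb8 by −2.39 (SE 0.50). Rhoj was higher by 3.04 (SE 0.53) and Mrvi1 by 2.40 (SE 0.37). Ccnb1ip1 was at the bottom of the scale on control replicate 2 and on all SRF-null arrays (4.0), against 10.7 and 11.4 on control replicates 1 and 3.

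Mocs1 was higher by 5.02 (SE 0.36) in SRF-null cells, from a dim control level. The second Mocs1 probe set differed by −0.72 (SE 0.50), so a transcript read by 1 probe set only, or cross-hybridisation of that probe set, stays open. DNA linked to Srf and carried along with the floxed allele is a candidate explanation, since Mocs1 lies 51 genes from Srf in gene order, and 7 of the 200 measured genes nearest to Srf, Mocs1 left out, had a p under 0.01, among them Xpo5 (−1.04), Tnfrsf21 (0.79), H2-M3 (0.95) and Satb1 (0.61). As many were found in 4.47% of windows of that size elsewhere (median 3), but these windows overlap and neighbouring genes can share regulation. Loss of SRF stays open as well, because genotype and linked DNA go together in this design.

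Actin cytoskeleton targets of SRF were called higher, not lower, as a list in cells labelled SRF-null, with a mean of 0.28 but a median of 0.08. A wrong scaling of the arrays would shift genes of the same level alike. The list exceeded unlisted genes of its level by 0.29 (SE 0.05) quantile normalized. On the values as deposited, whose scaling by the authors is not known, the excess was 0.29 (SE 0.06), which a shift of whole arrays leaves as it is. These values argue against scaling as the whole cause, although the list's own mean after median centring was 0.25 (SE 0.22). Without the arrays of 1 sex the mean did not fall, at 0.30 (SE 0.13) against 0.28 with all arrays. The call at the preset correlation was kept (camera adjusted p = 0.0290), while the interferon list turned. With all arrays the call was lost at an estimated correlation (camera adjusted p = 0.608). So few arrays remained per group that the arrays of 1 sex are not excluded as the whole cause. The share of males in the pools stays open, because Y-linked signal, relative to the male-only array, was 75.5% and 86.4% in the other SRF-null arrays against 35.6% and 51.5% in the other control arrays and left a mean of 0.34 (SE 0.19) as a covariate, although the male-only array had the lowest list mean of the SRF-null arrays (11.61) and the female-only array (11.37) not the lowest of the controls (11.30). Exchanged group labels could give the pattern and stay open, because Srf, though at −0.42 (SE 0.13) in the SRF-null arrays, was lower on 1 probe set only, whose place relative to the deleted part is not given in the sources used here, and an effect of SRF loss in the cells that persist after deletion was not separated from these.

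Monocyte and macrophage genes were called higher in SRF-null arrays at the preset correlation. That call was lost with an estimated correlation (camera adjusted p = 0.683) and without SRF-null replicate 3 (adjusted p = 0.0906). A lower share of LSK cells stays open. It would raise other markers alike only if the cells mixed in held every type in like shares, so the comparison with other lists cannot settle it. Low-level macrophage markers exceeded those of the 8 other cell type lists by 0.36 (SE 0.20), under 2 standard errors. They exceeded the single lists by −0.05 (SE 0.23, T and NK cells) to 0.75 (SE 0.41, stromal and endothelial cells, the 1 list whose low-level markers were lower, at −0.07), with 7 of 8 above 0 and each under 2 standard errors. These standard errors take no account of the replicate pairs. SRF-null replicate 3 had the highest mean of the macrophage, T and NK, B cell, dendritic, erythroid and granulocyte lists, but not of the mast cell, megakaryocyte or stromal lists. RNA of macrophages in the sorted cells stays open. Of 16 low-level macrophage markers 75% were higher (mean 0.68, SE 0.56), but so were 78 of 116 low-level markers of the 8 other cell type lists (mean 0.32, SE 0.41). How far the lineage-negative gate removed macrophages was not tested. The other 10 measured macrophage markers lay above the median level in LSK cells, and 4 of the 26 are also in another list. Of the bright ones Ctss differed by 0.75 (SE 0.18) and Lyz2, at 16.21 in control arrays, by −0.07 (SE 0.16). A change in the LSK cells themselves was not tested apart from RNA of macrophages.

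Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest other split 1. From a count of 0 all 10 of 10 splits had to give as many, so this count decides nothing. For genes at an unadjusted p under 0.05 the real split gave 1044 and 4 of 10 splits gave as many, the highest being 2274 for control 1, SRF-null 1 and SRF-null 2 against the other arrays, which points to a structure of the samples other than genotype. Those 3 arrays had the highest median signals before normalization, at 230.5 to 292.1 against 200.5 to 221.4. Whether this difference in signal is the cause was not tested. For lists called, the real split gave 8 and 3 of 10 splits gave as many, the highest other 9. Among the 4 splits that part all 3 number pairs, the real split gave 1044 genes at an unadjusted p under 0.05 against 410 to 621 and 8 lists against 1 to 6, while the other 6 splits part 1 pair and keep a pair together on each side. The real split is 1 of only 4 here, and the pairs were read from these same arrays, so this ranking cannot exclude chance.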
